A study of Mus musculus with 6 samples.

How the data were processed

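Liver RNA of male C57BL/6J mice, a common inbred laboratory strain, was measured by RNA sequencing in 6 libraries. Per the labels' protocols, total RNA was taken from homogenised liver with Trizol, a phenol-based reagent, and Illumina libraries were made from it. The labels place 3 libraries in a group called re-fed and 3 in a group fasted for 48 h. The sample labels and the series' design text say re-fed, but the treatment protocol in the same labels speaks of normal feeding or fasting, so whether the mice of the first group had been fasted before feeding is not settled. That group is called refed here, after its sample labels.

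The deposited table holds 23631 Ensembl genes with 4 kinds of values made by the authors. Whether any sample or group was left out before this table was made is not given in the sources used here. Per the file headers, the authors deposited raw read counts per gene, and these whole numbers are the counts used here. Per the file headers, the authors also deposited a normalized signal and the same signal divided by gene length in kb. Within each library the deposited count divided by the deposited normalized signal was a single constant, that is, a size factor per library. The authors' log2 fold change of fasted over refed, their p-value and their adjusted p-value stand in the same deposited table, per the file headers. The submitters' processing notes name TopHat2 2.0.10, Bowtie2 2.1.0, HTSeq 0.5.4p3, DESeq2 1.0.19 and the genome build mm9, without roles. Counting settings, strand handling and the annotation release are not given in the sources used here. Reads of overlapping or antisense genes, and of near-identical gene copies, may therefore be split or lost, and values of such genes are uncertain. Coordinates are those of the deposited table (mm9). The annotation at hand was of another build, GRCm38, and only 280 of 21970 shared gene identifiers had the same start and end there, so none of its coordinates was used.

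Every row names a gene, and each column of counts names 1 library by its group and replicate number. The 1199 genes with no read in any library are the same 1199 genes that have no value in the authors' comparison. Total counts per library ranged from 29574528 to 36026753. Levels are given as CPM, the count scaled to a common library size, and 3 counts, taken as the floor, correspond to between 0.0833 and 0.101 CPM. Pairs of libraries were compared by chi-square over genes, and no pair differed by as little as sampling noise, so none was treated as a duplicate.

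Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group and its minimum count of 10, which left 13248 and removed 10383. Library sizes were scaled with TMM factors. Robust quasi-likelihood fits (glmQLFit, glmQLFTest) had the group as the only term. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called changed at an adjusted p under 0.05. Log2 fold changes are fasted minus refed, and the standard error is the log2 fold change divided by the square root of the quasi-likelihood F statistic. CPM values use TMM-scaled library sizes and are given as mean ± SD over 3 libraries. The labels number the samples but do not say how they were taken from animals. The p-values therefore measure only the spread between these samples, which may be technical.

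Before the data were examined, 19 pathway lists and 12 cell type lists were fixed, together with the tests, the alternatives and the rule for named genes. Members were looked up by symbol in the deposited table, with older symbols where needed. Each list was tested with camera (limma 3.58.1), which compares the members with all other tested genes, at a preset correlation of 0.01 and again with an estimated correlation. Its p-values were adjusted over the 19 pathway lists or over the 10 cell type lists that had at least 3 tested members. Members counted as rising or falling passed edgeR's test over all tested genes, and the counts adjusted over the list alone stand beside them. The rule named 43 genes. It took the 3 highest and 3 lowest log2 fold changes among called genes of at least 5 CPM whose groups did not overlap. It took the members with the lowest p of each list (2 from the first 9 pathway lists, 1 from the others), the called member that went against each of those 9 lists, and 1 member of any cell type list of which at least 50 percent of the members passed. Results for some of these genes and of the list members are not reported here. Other list members named in the text were chosen after their values were seen. Of the list members, Hmgcs1 and some globin and pancreas genes were not analysed here.

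The alternatives were DESeq2 1.42.0, limma-voom, other scaling factors, other count filters, a test against a log2 change of 0.5 (glmTreat), the replicate number as a block, and each library left out. The lists were repeated under the scaling, filter, block and leave-one-out settings. Alternatives added after seeing the data were the list counts without fasted replicate 3 and the male-predominant list without families of near-identical copies. Each library was also set against the other libraries of its group, as differences of log2(CPM + 0.5). Gene Ontology terms of the deposited table with 15 to 300 tested genes were tested with camera among the 9454 tested genes that carried a term. This test was also chosen after the data were seen. Tables were joined and plots drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

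The count tests were tested on simulated data for the fasted against refed comparison, with 13248 genes of the real means and library sizes, 200 of them changed. edgeR recovered 7.5% of the genes changed 1.5-fold, 59.7% of those changed 2-fold and 90.9% of those changed 4-fold, and 13.2% of its calls were false. DESeq2 recovered 68.7% at 2-fold, with 24.3% of its calls false. Only 200 genes were changed, against 7866 called in the real data, so these shares need not hold there. Camera found 20 of 20 changed simulated sets and called 0 of 100 unchanged ones. The simulated genes were drawn independently, so this could not test camera on lists whose members vary together. The estimated correlation was 0.91 in the oxidation list and 0.774 in the PPARalpha-regulated list.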

Results

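RNA sequencing gave counts per gene for 6 mouse liver libraries, 3 labelled refed and 3 labelled fasted for 48 h. The comparison between them asks which liver transcripts differ between the fed and the fasted state. Total counts were 31730209 ± 1875568 (SD, n = 3) in refed and 35339163 ± 1017354 (SD, n = 3) in fasted libraries, with 18154 to 18699 genes detected per library. Albumin (Alb), the main plasma protein made by hepatocytes, took the most counts in each library, at 8.11% ± 0.939 in refed and 7.27% ± 0.526 in fasted livers (SD, n = 3). Mitochondrial genes took 7.63% ± 0.497 and 7.66% ± 0.828 (SD, n = 3). The first principal component of log2 CPM held 82.6% of the variance and separated the groups. The second held 9.29% and separated fasted replicate 3, at 48.7, from fasted replicates 1 and 2, at -26.0 and -19.8. The chi-square per gene was 35.7 between fasted replicates 1 and 2 and 236 and 211 between each of them and fasted replicate 3, against 26.8 to 48.6 among refed libraries.

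Fasted and refed livers differed in most of the genes tested. Among called genes of at least 5 CPM whose groups did not overlap, the highest rises were those of Wnt11, a secreted Wnt ligand, Mt2, a metallothionein that binds zinc and copper, and Ppp1r3g, which targets protein phosphatase to glycogen. Mt2 rose from 4.0 ± 1.02 CPM to 1325 ± 377 CPM and Ppp1r3g from 0.472 ± 0.333 CPM to 132 ± 71.4 CPM (SD, n = 3 each). Wnt11 had 2 reads in all refed libraries together and 1757 in the fasted ones, a ratio of 915 with a 95% exact counting interval from 253 to 7561, which covers counting error only. Among the deepest falls by the same rule were those of the pseudogene Serpina4-ps1 and of Hsd3b5, a steroid dehydrogenase of male liver. Hsd3b5 fell from 173 ± 33.1 CPM to 0.205 ± 0.141 CPM (SD, n = 3). Serpina4-ps1 fell from 328 ± 209 CPM to 0.357 ± 0.233 CPM (SD, n = 3), and may share reads with other serpin genes. Its log2 fold change was -9.83, or -10.46 without fasted replicate 3.

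Wnt11 (ENSMUSG00000015957) lies on chromosome 7 from 105983622 to 106003705 (mm9), Mt2 (ENSMUSG00000031762) on chromosome 8 from 96696518 to 96697467, and Ppp1r3g (ENSMUSG00000050423) on chromosome 13 from 36050708 to 36062257. Serpina4-ps1 (ENSMUSG00000092075) lies on chromosome 12 from 105318859 to 105324934 and Hsd3b5 (ENSMUSG00000038092) on chromosome 3 from 98422559 to 98434232. The deposited counts are given per gene, so no exon or UTR is singled out. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave an adjusted p of 2.39e-06 for Wnt11, 3.68e-06 for Mt2, 6.26e-05 for Ppp1r3g, 9.92e-05 for Serpina4-ps1 and 3.96e-06 for Hsd3b5.

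Of 13248 genes tested, edgeR called 7866 changed (59.4%), 3867 higher and 3999 lower in fasted livers. Changes of at least 2-fold were found in 1931 higher and 2270 lower genes, and of at least 8-fold in 216 higher and 279 lower genes. The 3 fasted libraries lay all above or all below the 3 refed ones in 67.2% of tested genes, where chance gives 10%. The authors' deposited table holds 8849 genes with an adjusted p under 0.05, 4445 higher and 4404 lower, among 22432 genes with a value. Of the genes called here, 7805 were called in the same direction and 0 in the opposite direction in the authors' deposited table. With library totals in place of TMM factors the split was 2873 higher and 5074 lower, and the median log2 fold change of all tested genes lay at -0.21. Changes are therefore relative to the bulk of the tested genes.

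**Figure D1:**
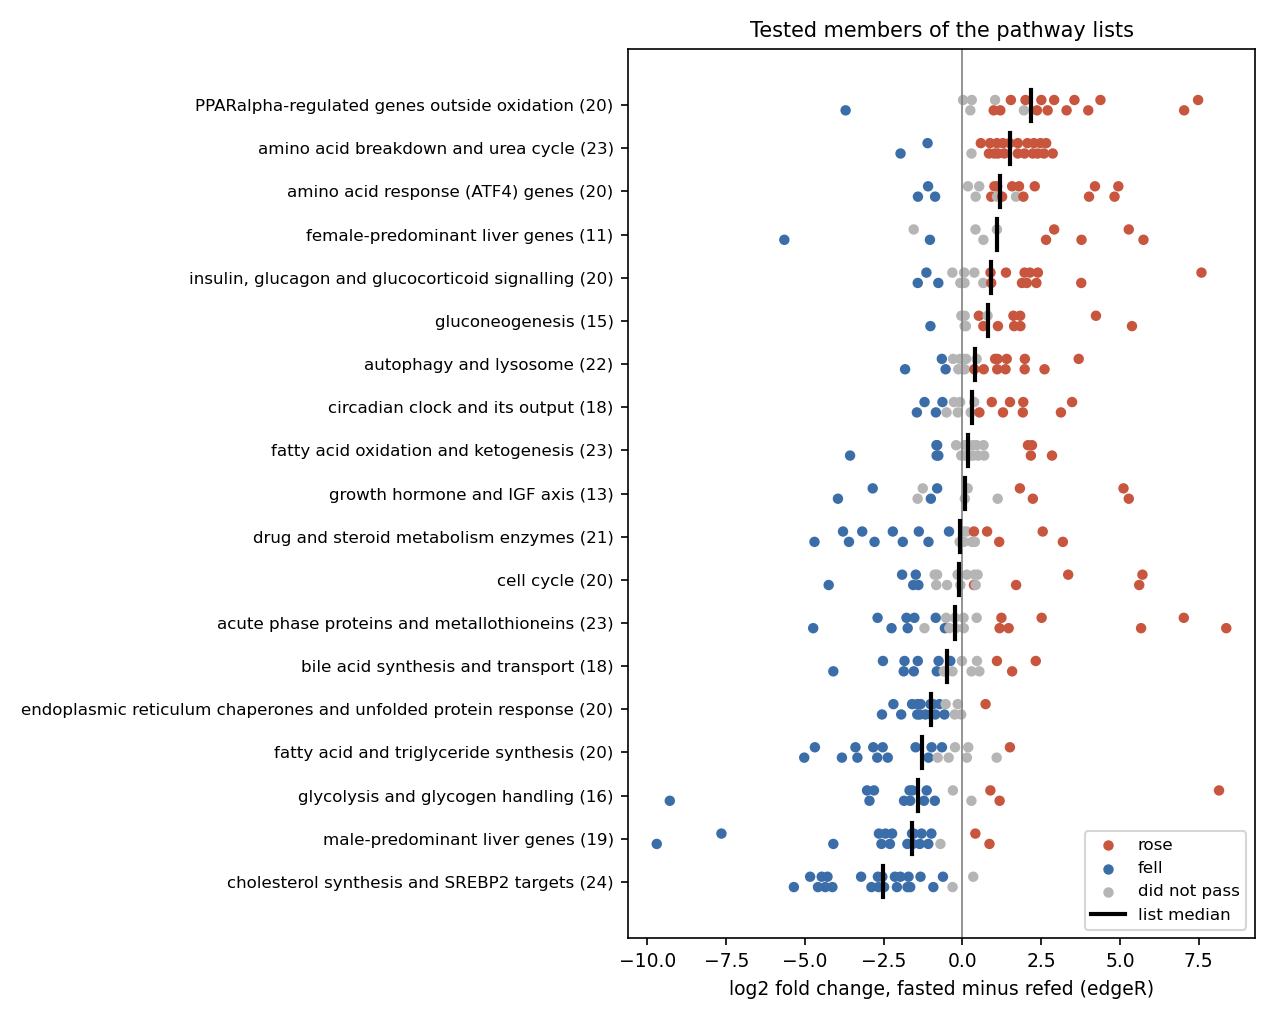
Log2 fold change (x axis, fasted minus refed, edgeR) of each tested member of the 19 pathway lists (y axis, number of tested members in brackets). Points are genes, coloured by whether they rose, fell or did not pass the test, and black bars are list medians, from -2.52 for cholesterol synthesis to 2.18 for PPARalpha-regulated genes.

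Genes regulated by PPARalpha, the nuclear receptor for fatty acids, rose as a group outside the oxidation enzymes themselves. Of 20 tested members, 14 rose, 1 fell and 5 did not pass, and the counts adjusted over the list alone were the same 14 and 1. The median log2 fold change was 2.18 (camera adjusted p = 0.000978; adjusted p = 0.522 with an estimated correlation). Cyp4a14, a fatty acid omega-hydroxylase, rose from 984 ± 229 CPM to 11562 ± 4476 CPM (SD, n = 3; log2 fold change 3.55, SE 0.35, edgeR adjusted p = 0.00011). Its relative Cyp4a32 rose from 16.2 ± 3.34 to 106 ± 28.1 CPM (SD, n = 3; log2 fold change 2.70, SE 0.24, edgeR adjusted p = 7.52e-05). The Cyp4a genes are close copies, so the split of reads among them is uncertain. Fabp1, the main fatty acid binding protein of liver, was the member that fell, from 3477 ± 520 CPM to 266 ± 161 CPM (SD, n = 3; log2 fold change -3.71, SE 0.55, edgeR adjusted p = 0.000909).

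Enzymes of fatty acid oxidation and ketogenesis did not pass as a group when all libraries were used. Of 23 tested members, 4 rose (Cpt1a, Ehhadh, Acot1 and Acot2), 5 fell (Bdh1, Cpt2, Hadh, Acaa2 and Acaa1b) and 14 did not pass. Adjusted over the list alone, 4 rose and 4 fell. The median log2 fold change was 0.19, or -0.04 with library totals (camera adjusted p = 0.853; adjusted p = 0.966 with an estimated correlation). Cpt1a, the gate of fatty acid entry into mitochondria, rose from 274 ± 85.4 to 1160 ± 272 CPM (SD, n = 3; log2 fold change 2.08, SE 0.27, edgeR adjusted p = 0.000374). Bdh1, which interconverts the ketone bodies, fell from 199 ± 18.2 to 16.8 ± 7.99 CPM (SD, n = 3; log2 fold change -3.57, SE 0.38, edgeR adjusted p = 0.000187). It overlaps Gm15743.

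Fasted replicate 3 lay below the mean of the other fasted libraries in 20 of 20 PPARalpha-regulated genes and in 23 of 23 oxidation genes, by a median log2 difference of -1.61 and -1.07. Without fasted replicate 3, 15 oxidation genes rose and 5 fell, with a median of 0.49 (camera adjusted p = 0.0146; range over all alternatives 0.0146 to 0.982). Without any 1 of the other libraries, 1 oxidation gene rose and 4 or 5 fell, and the median came down to 0.08 without fasted replicate 1 and 0.01 without fasted replicate 2. For the PPARalpha-regulated list, 18 rose and 1 fell without fasted replicate 3, with a median of 2.66.

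**Figure D2:**
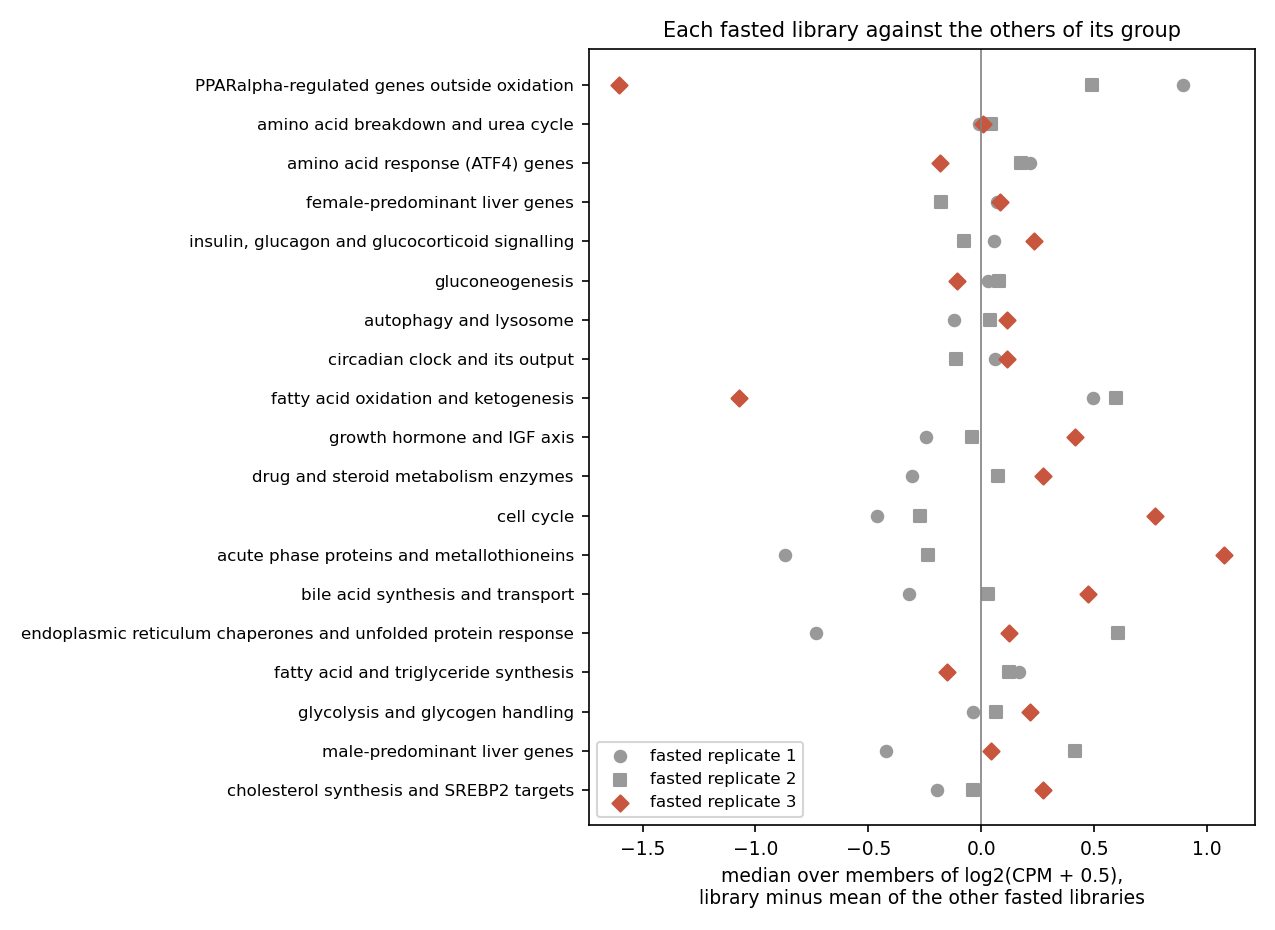
Median difference in log2(CPM + 0.5) between each fasted library and the mean of the other fasted libraries (x axis) for the 19 pathway lists (y axis), with 1 marker per library. Fasted replicate 3 lies lowest for PPARalpha-regulated genes (-1.61) and for oxidation genes (-1.07), and highest for the acute phase list (1.08).

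Genes of gluconeogenesis rose as a group, with 9 of 15 tested members up, 1 down and 5 that did not pass, and the same 9 and 1 when adjusted over the list alone. The median log2 fold change was 0.80 (camera adjusted p = 0.00129; adjusted p = 0.0956 with an estimated correlation). Got1, the cytosolic aspartate aminotransferase, rose from 111 ± 7.85 to 4620 ± 611 CPM (SD, n = 3; log2 fold change 5.38, SE 0.19, edgeR adjusted p = 2.39e-06). Got1 (ENSMUSG00000025190) lies on chromosome 19 from 43574242 to 43599095 (mm9). Slc37a4, the glucose-6-phosphate transporter, rose 3.58-fold to 900.4 ± 102 CPM (SD, n = 3; edgeR adjusted p = 4.27e-05). The glycerol-3-phosphate dehydrogenase Gpd1, which overlaps Gm16537, fell 2.02-fold (log2 fold change -1.02, SE 0.37, edgeR adjusted p = 0.046). Its call was lost without any 1 refed library and without fasted replicate 2 (edgeR adjusted p from 0.0723 to 0.103; range over all alternatives 0.00125 to 0.154). G6pc, the catalytic subunit of glucose-6-phosphatase, had a log2 fold change of -0.04 (SE 0.16) and did not pass.

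Enzymes of amino acid breakdown and the urea cycle rose nearly throughout. Of 23 tested members, 20 rose, 2 fell (Otc and Glud1) and 1 did not pass (Prodh), and the counts adjusted over the list alone were also 20 and 2. Its median log2 fold change was 1.5 (camera adjusted p = 5.92e-07; adjusted p = 0.0495 with an estimated correlation). Sdsl, a serine dehydratase-like enzyme, rose from 10.3 ± 0.918 to 75.2 ± 14.4 CPM (SD, n = 3; log2 fold change 2.86, SE 0.16, edgeR adjusted p = 8.07e-06). Asl, the argininosuccinate lyase of the urea cycle, rose from 770.3 ± 26.9 to 4287 ± 184 CPM (SD, n = 3; log2 fold change 2.48, SE 0.15, edgeR adjusted p = 9.42e-06). Otc, the ornithine transcarbamylase of the same cycle, fell from 515 ± 15.2 to 132 ± 24.8 CPM (SD, n = 3; log2 fold change -1.97, SE 0.17, edgeR adjusted p = 4.61e-05).

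Cholesterol synthesis had the lowest median of the pathway lists. Of its 24 tested members 22 fell, 0 rose and 2 did not pass (Hsd17b7 and Ebp) by edgeR over all tested genes, and the counts adjusted over the list alone were the same. Without fasted replicate 3, 23 fell and 1 rose. Members had a median log2 fold change of -2.52 (camera adjusted p = 2.38e-24; adjusted p = 0.0495 with an estimated correlation). Sqle, the squalene epoxidase, fell from 140 ± 23.5 to 3.42 ± 0.129 CPM (SD, n = 3; log2 fold change -5.35, SE 0.17, edgeR adjusted p = 2.39e-06). Sqle (ENSMUSG00000022351) lies on chromosome 15 from 59146632 to 59162747 (mm9). Idi1, an isomerase of the same pathway, fell from 32.3 ± 2.92 to 1.58 ± 0.139 CPM (SD, n = 3; log2 fold change -4.36, SE 0.15, edgeR adjusted p = 2.39e-06).

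Fatty acid and triglyceride synthesis genes fell in 13 of 20 tested members, with 1 that rose and 6 that did not pass, and likewise 13 and 1 when adjusted over the list alone. At the median, the log2 fold change was -1.28 (camera adjusted p = 2.27e-05; adjusted p = 0.121 with an estimated correlation). Elovl6, an elongase of long-chain fatty acids, fell 14.2-fold to 15.1 ± 4.21 CPM (SD, n = 3; edgeR adjusted p = 9.99e-06). Without refed replicate 1, 2 members of this list rose. Acaca, the acetyl-CoA carboxylase, fell 7.13-fold to 18.6 ± 1.44 CPM (SD, n = 3; edgeR adjusted p = 6.84e-06), in a locus shared with Gm11437 and Gm17722. Elovl5, an elongase of polyunsaturated fatty acids, was the member that rose, from 183 ± 12.2 to 519 ± 244 CPM (SD, n = 3; edgeR adjusted p = 0.00852).

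Glycolysis and glycogen genes mostly fell, with 11 of 16 tested members down, 3 up (Ppp1r3g and Gys2 among them) and 2 that did not pass. Adjusted over the list alone, 12 fell and 3 rose, and without refed replicate 3 only 1 rose. Over the list, the median log2 fold change was -1.41 (camera adjusted p = 9.48e-05; adjusted p = 0.0732 with an estimated correlation). Within this list 2 glycogen-targeting subunits of protein phosphatase fell and 1 rose. Ppp1r3b fell from 457 ± 46.0 to 65.2 ± 3.40 CPM (SD, n = 3; log2 fold change -2.81, SE 0.14, edgeR adjusted p = 6.05e-06), and Ppp1r3c from 30.6 ± 5.38 to 3.75 ± 1.59 CPM (SD, n = 3; log2 fold change -3.03, SE 0.31, edgeR adjusted p = 0.000167). Ppp1r3g rose by a log2 fold change of 8.14 (SE 0.65), or 8.84 without refed replicate 1 (range over all alternatives 7.69 to 8.84).

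**Figure D3:**
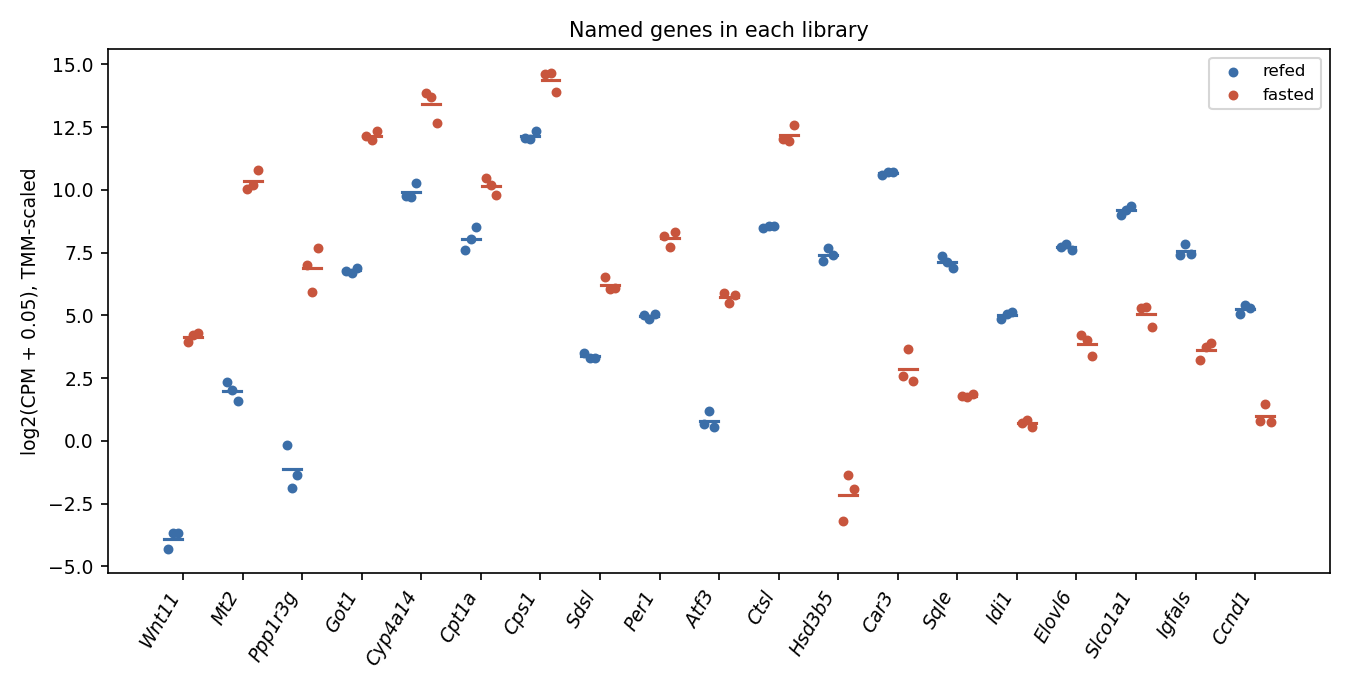
Level of 19 named genes (x axis) in each library as log2(CPM + 0.05) with TMM scaling (y axis). Points are the 3 libraries of a group and bars their means; Hsd3b5 falls from 173 to 0.205 CPM and Got1 rises from 111 to 4620 CPM.

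Bile acid genes moved in both directions: of 18 tested members 3 rose (Cyp8b1, Abcb4 and Abcg8), 9 fell and 6 did not pass, with the same counts adjusted over the list alone. Its median log2 fold change was -0.49 (camera adjusted p = 0.277; adjusted p = 0.635 with an estimated correlation). Slco1a1, a bile acid and steroid uptake transporter, fell from 587 ± 71.1 to 34.2 ± 9.48 CPM (SD, n = 3; log2 fold change -4.10, SE 0.25, edgeR adjusted p = 1.02e-05), at a locus where the table also lists a 7SK gene. Cyp8b1, the sterol 12-alpha-hydroxylase, rose from 275 ± 93.7 to 1378 ± 408 CPM (SD, n = 3; log2 fold change 2.33, SE 0.31, edgeR adjusted p = 0.000488). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had 5.94 and 8.63 CPM in fasted replicates 1 and 2 but 471 CPM in fasted replicate 3, against 141 to 323 CPM in refed livers, and did not pass. Without fasted replicate 3, 3 members rose, 10 fell and the list passed (camera adjusted p = 0.04; range over all alternatives 0.04 to 0.635), while without fasted replicate 1 its median was -0.25.

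Clock genes and their outputs rose in 8 of 18 tested members, fell in 4 (Cry1, Hlf and Per2 among them) and did not pass in 6, with the same counts adjusted over the list alone. Members had a median log2 fold change of 0.32, or 0.16 without refed replicate 1 and 0.10 with library totals, and the list did not pass (camera adjusted p = 0.131). Gm129, also known as Ciart, a repressor of the clock, rose from 5.76 ± 0.347 to 64.2 ± 11.98 CPM (SD, n = 3; log2 fold change 3.48, SE 0.16, edgeR adjusted p = 5.17e-06), and overlaps C920021L13Rik. Per1 rose 8.72-fold (edgeR adjusted p = 8.4e-06) and Cry1 fell 2.31-fold (edgeR adjusted p = 0.000169). The labels used here give no hour of collection.

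Genes of insulin, glucagon and glucocorticoid signalling rose in 11 of 20 tested members, fell in 3 (Irs1, Tsc22d3 and Creb1) and did not pass in 6, with the same counts adjusted over the list alone. At the median, the log2 fold change was 0.90 (camera adjusted p = 0.00507; adjusted p = 0.143 with an estimated correlation). Klf9, a transcription factor induced by glucocorticoids, rose from 49.1 ± 5.37 to 216 ± 7.50 CPM (SD, n = 3; edgeR adjusted p = 9.42e-06), in a locus shared with Mir1192. The growth hormone and IGF list held 4 genes that rose (Igfbp1, Igfbp2, Igfbp3 and Cux2), 4 that fell (Igf1, Igfals, Ghr and Stat5a) and 5 that did not pass, with the same counts adjusted over the list alone. Its median log2 fold change was 0.07, or -0.13 with library totals and from -0.17 to 0.19 with 1 library left out, and it did not pass (camera adjusted p = 0.587). Igfals, which carries IGF in plasma, fell from 192 ± 34.9 to 12.4 ± 2.93 CPM (SD, n = 3; edgeR adjusted p = 9.08e-06).

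Genes known to be higher in male than in female liver fell in 16 of 19 tested members, rose in 2 (Cyp2d9 and Cyp4a12b) and did not pass in 1 (Mup20), and 17 fell and 2 rose when adjusted over the list alone. Over the list, the median log2 fold change was -1.60 (camera adjusted p = 3.15e-07; adjusted p = 0.0956 with an estimated correlation). Hsd3b5 had the lowest p of this list. Only 1 member rose without any 1 refed library or without fasted replicate 2. Several members, the Mup genes among them, belong to families of near-identical copies whose counts are uncertain. Genes known to be higher in female liver rose in 5 of 11 tested members (Fmo2, Cyp17a1, Cux2 and Cyp4a10 among them), fell in 2 (A1bg and Abcd2) and did not pass in 4, with the same counts adjusted over the list alone. Their median was 1.09 (camera adjusted p = 0.0441; adjusted p = 0.296 with an estimated correlation), and the call was lost without refed replicate 1 (camera adjusted p = 0.0561; range over all alternatives 0.00157 to 0.296). The median was 0.71 without refed replicate 1, 1.67 without refed replicate 3 and 2.88 at a mean of at least 5 CPM, and 1 member fell without any 1 of refed replicates 2 and 3 and fasted replicates 2 and 3. Cyp4a10 is also in the PPARalpha-regulated list and Cux2 in the growth hormone list. Fmo2, a flavin monooxygenase, rose from 25.2 ± 6.61 to 158 ± 29.6 CPM (SD, n = 3; edgeR adjusted p = 5.73e-05).

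Drug and steroid metabolism enzymes fell in 10 of 21 tested members, rose in 5 (Cyp2b10, Por, Cyp3a13, Cyp3a25 and Ugt1a1) and did not pass in 6, with the same counts adjusted over the list alone. Its median log2 fold change was -0.09 (camera adjusted p = 0.0382; adjusted p = 0.481 with an estimated correlation). The call was lost without fasted replicate 1 or without fasted replicate 2 (camera adjusted p = 0.0591 and 0.0514; range over all alternatives 0.00219 to 0.481), and with 1 library left out the median ran from -0.48 (fasted replicate 3) to 0.06 (fasted replicate 1). Without refed replicate 2, 2 members rose and 8 fell. Ugt2b1, a glucuronosyltransferase, fell from 963 ± 11.96 to 69.5 ± 8.80 CPM (SD, n = 3; log2 fold change -3.79, SE 0.16, edgeR adjusted p = 3.68e-06).

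Chaperones of the endoplasmic reticulum and unfolded protein response genes fell in 15 of 20 tested members, rose in 1 (Herpud1) and did not pass in 4, with the same counts adjusted over the list alone. Members had a median log2 fold change of -1.01 (camera adjusted p = 0.0121; adjusted p = 0.522 with an estimated correlation). The fasted libraries split on this list. Against the mean of the others, fasted replicate 2 lay higher by a median log2 difference of 0.61 and fasted replicate 1 lower by -0.73, in 20 of 20 members. Hspa5, the main chaperone of that compartment, did not pass, at 2530 CPM in fasted replicate 2 and 1071.5 and 928 CPM in fasted replicates 1 and 3, against 1910 to 2620 CPM in refed libraries. Without refed replicate 2, 0 members rose. Without fasted replicate 2, 17 members fell (camera adjusted p = 8.62e-06; range over all alternatives 8.62e-06 to 0.522). Sel1l, a component of the degradation machinery of that compartment, fell from 246 ± 48.5 to 96.2 ± 16.8 CPM (SD, n = 3; edgeR adjusted p = 0.000438). Genes of the amino acid response driven by ATF4 rose in 12 of 20 tested members, fell in 3 (Psph, Shmt2 and Mthfd2, enzymes of serine and one-carbon metabolism) and did not pass in 5, with the same counts adjusted over the list alone. Their median was 1.18 (camera adjusted p = 0.000346; adjusted p = 0.121 with an estimated correlation). Atf3, a stress-induced transcription factor, rose from 1.73 ± 0.432 to 53.5 ± 7.35 CPM (SD, n = 3; edgeR adjusted p = 3.68e-06). Autophagy and lysosome genes rose in 11 of 22 tested members, fell in 3 (Ulk2, Ctsb and Vps18) and did not pass in 8, with the same counts adjusted over the list alone. Their median was 0.41, or 0.20 with library totals (camera adjusted p = 0.00639; adjusted p = 0.157 with an estimated correlation). Ctsl, a lysosomal protease, rose from 369 ± 12.4 to 4766 ± 1150 CPM (SD, n = 3; edgeR adjusted p = 8.94e-06).

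Acute phase proteins and metallothioneins went both ways, with 7 of 23 tested members up, 8 down and 8 that did not pass, and the same counts adjusted over the list alone (camera adjusted p = 0.387). Without refed replicate 1, 6 rose and 5 fell. Their median log2 fold change was -0.24, but their mean was 0.40 and camera's direction was up. Fasted replicate 3 lay above the mean of the other fasted libraries in 23 of 23 members of this list, by a median log2 difference of 1.08, and fasted replicate 1 lay below it in 23 of 23, by -0.87. Without fasted replicate 3 the median was -0.77, with 7 up and 10 down, and without fasted replicate 1 it was -0.01, with 7 up and 6 down. Cell cycle genes rose in 5 of 20 tested members (Cdkn1a, Gadd45a, Gadd45b, Ccne1 and Pcna), fell in 5 (Ccnd1, Cdk1, Aurka, Mcm5 and Mcm6) and did not pass in 10, and 4 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.423). The first 3 of those that rose are induced under stress and hold back the cycle. With 1 library left out, the cell cycle median ran from -1.40 (fasted replicate 3) to 0.36 (fasted replicate 1), against -0.11 with all. Without fasted replicate 3, 4 rose and 10 fell, and without any 1 of refed replicates 2 and 3 and fasted replicates 1 and 2, 3 fell. Ccnd1, cyclin D1, fell from 38.2 ± 4.78 to 2.01 ± 0.600 CPM (SD, n = 3; edgeR adjusted p = 6.29e-06), and overlaps Oraov1.

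Of the 10 cell type lists tested, camera passed 0 (adjusted p from 0.0972 to 0.919), with 1 of them, the pericentral one, below an unadjusted p of 0.05. Hepatocyte markers rose in 4 of 10 tested members (Apoa1, Cps1, Ahsg and Hnf4a), fell in 3 (Apob, Ttr and Trf) and did not pass in 3, at a median log2 fold change of 0.20, or -0.02 with library totals. Cps1, the carbamoyl phosphate synthetase of the urea cycle, rose from 4592 ± 588 to 22099 ± 6034 CPM (SD, n = 3; edgeR adjusted p = 0.000139). Kupffer cell and macrophage markers fell in 1 of 12 (Emr1) and did not pass in 11, at a median of -0.40. Endothelial markers rose in 3 of 11 (Stab1, Pecam1 and Lyve1) and did not pass in 8, at a median of 0.28. Stellate cell and fibroblast markers rose in 2 (Dcn and Ecm1), fell in 2 (Lrat and Col3a1) and did not pass in 7, at a median of 0.06, or -0.15 with library totals. Bile duct markers rose in 2 of 6 (Epcam, and Sox9 from 2.30 ± 0.179 to 4.55 ± 0.290 CPM, SD, n = 3), fell in 1 (Spp1) and did not pass in 3, at a median of -0.40. Lymphocyte markers rose in 1 of 3 (Cd79b), fell in 1 (Cd4, from 1.99 ± 0.238 to 0.183 ± 0.0921 CPM, SD, n = 3) and did not pass in 1, at a median of -0.76. Neutrophil markers rose in 1 of 3 (S100a9, at 71.4 CPM in fasted replicate 3 and at most 0.683 CPM in the other libraries) and did not pass in 2, at a median of 0.97. Erythroid markers fell in 1 of 6 (Alas2) and did not pass in 5, at a median of 0.15, or -0.06 with library totals. Of the 2 tested adipocyte markers Car3, a carbonic anhydrase that hepatocytes also express, fell from 1626 ± 91.4 to 7.91 ± 4.14 CPM (SD, n = 3; edgeR adjusted p = 1.06e-05), and of the 2 tested pancreas markers Cela1 fell 4.03-fold (edgeR adjusted p = 7.1e-05). Adjusted over the list alone, 0 Kupffer cell and 0 neutrophil markers passed, 2 endothelial markers rose, and 1 bile duct marker rose and 1 fell, while the other cell type counts stayed the same. Fasted replicate 1 lay below the mean of the other fasted libraries in 12 of 12 Kupffer cell markers, by a median log2 difference of -1.57, and in 11 of 11 endothelial ones, by -0.62. In the refed group, replicate 1 lay below in 11 of 11 endothelial markers, by -0.65, and replicate 3 above in 11 of 11, by 0.70. Without fasted replicate 1, 2 Kupffer cell markers rose and 1 fell, at a median of -0.01, and 3 neutrophil markers rose. Without fasted replicate 3, 4 Kupffer cell markers, 2 lymphocyte markers and 2 erythroid markers fell. In the lymphocyte list 1 marker rose without refed replicate 2, but 0 rose without any other single library, with library totals, with upper quartile factors or with the block. With 1 library left out, medians ran from 0.05 to 0.585 for endothelial, -0.05 to 0.23 for stellate cell and -0.09 to 0.34 for erythroid markers. They ran from -1.34 to -0.19 for lymphocyte and 0.54 to 4.89 for neutrophil markers. The count filter was rerun each time, so the members tested could change. The neutrophil list held 4 tested members where its median was 3.98 or higher, and 3 where it was 0.85 or 0.54. The lymphocyte list held 3 or 4. The Kupffer cell median was -0.80 without fasted replicate 3 and the bile duct median -0.20 without fasted replicate 2. Only 1 bile duct marker rose without any 1 of refed replicates 2 and 3 and fasted replicates 1 and 3, and 0 fell without any 1 of refed replicates 1 and 2 and fasted replicates 2 and 3. Without fasted replicate 2, 2 erythroid markers rose, and 0 neutrophil markers rose without any 1 refed library.

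Markers of both hepatocyte zones went both ways, and neither list passed camera in the main analysis. Pericentral markers rose in 2 of 12 tested members (Oat and Slc1a2), fell in 5 (Cyp1a2, Lgr5, Gulo, Lect2 and Slc13a3) and did not pass in 5, at a median log2 fold change of -0.36 (camera adjusted p = 0.0972; adjusted p = 0.967 with an estimated correlation). This list passed without refed replicate 1, fasted replicate 2 or fasted replicate 3 (camera adjusted p = 0.042, 0.0406 and 0.0405; range over all alternatives 0.00446 to 0.967). Its median was -0.19 without fasted replicate 1 and -0.60 without fasted replicate 3. Periportal markers rose in 6 of 12, fell in 4 (Cyp2f2, Ctsc, Sult5a1 and Pigr) and did not pass in 2, at a median of 0.63 (camera adjusted p = 0.566). Of those that rose, Hal, Sds, Gls2, Ass1 and Arg1 are also in the amino acid breakdown and urea cycle list, as is the pericentral Oat. None of the 4 periportal markers that fell is in it. The periportal rises therefore largely repeat the rise of that list. Cyp1a2 fell from 572 ± 118 to 22.0 ± 3.66 CPM (SD, n = 3; edgeR adjusted p = 5.35e-06) and Ass1, the argininosuccinate synthase, rose from 1825 ± 121 to 6161 ± 116 CPM (SD, n = 3; edgeR adjusted p = 4.34e-05). Adjusted over the list alone, the zone counts were the same. The median, mean and camera direction differed in sign for the growth hormone, acute phase, cell cycle, stellate cell, bile duct and erythroid lists, and in none of the other lists.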

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

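The direction and call of 42 of the 43 named genes held in every alternative that gave them a value. Gpd1 lost its call in 6 of 16. The rule named these genes by a low p or a large change in the same counts, so their stability was largely built in. Against a log2 change of 0.5 (glmTreat), 4929 genes passed, 2338 higher and 2591 lower, as that test asks for a larger change. The other counts of changed genes lay within 1.5 times the main count, at 7861 with DESeq2, 7846 with limma-voom, 7898 with DESeq2's size factors, 7947 with library totals, 7839 with upper quartile factors, 7873 without the 20 most abundant genes in the scaling, 8089 with no filter and 5672 at a mean of at least 5 CPM. Leaving out each library in turn gave 6562 to 8712 changed genes, 3151 to 4281 of them higher and 3411 to 4431 lower. No gene called in the main analysis was called in the opposite direction in any of these settings. With the replicate number as a block, 7340 genes passed. The values gave no sign that the numbers pair the samples. Same-numbered libraries had correlations of -0.016, -0.062 and -0.081 between their deviations from the group means. No library correlated best with its own number. The labels do not say whether samples were paired, and 3 libraries per group are too few to settle it.

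The 13 pathway lists that passed at the preset correlation were 2 with an estimated correlation, amino acid breakdown and cholesterol synthesis. Apart from that setting, 23 of 29 tested lists kept their call in each alternative run. The cell cycle list passed at a mean of at least 5 CPM (6 members left, median 1.89, camera adjusted p = 0.0218; range over all alternatives 0.0218 to 0.832), the pericentral list with no filter (camera adjusted p = 0.00446), and the drug metabolism list did not pass with library totals or at 5 CPM (camera adjusted p = 0.0559 and 0.0887). The cause of these changes was not tested. Medians with library totals were -0.44 for the acute phase, -0.30 for the drug metabolism, -0.31 for the cell cycle, -0.605 for the Kupffer cell, 0.07 for the endothelial, -0.61 for the bile duct, -0.57 for the pericentral and 0.42 for the periportal list. The neutrophil median was 7.60 with no filter and 7.85 at a mean of at least 5 CPM. The lymphocyte median was -0.42 with no filter, and the erythroid median -0.23 with no filter and 0.26 at 5 CPM. These filters changed the members tested: with no filter the neutrophil list held 9 and the lymphocyte list 12, against 3 each in the main analysis. Library totals gave autophagy counts of 9 up and 5 down and bile duct counts of 1 up and 2 down. The lists were not run with DESeq2, limma-voom or glmTreat. Simulated changes of 1.5-fold were mostly missed. Far fewer genes were changed in the simulation than were called in the real data, so this need not hold there.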

Other observations

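The tests of the fasted replicate 3 pattern, of the male-predominant list and of a common scaling shift, the Gene Ontology test, and the genes named here were chosen after the values were seen. Several of the most abundant transcripts changed their share of all counts, while Apoe, Cyp2e1 and Sepp1 kept similar ones. Mat1a, the liver's methionine adenosyltransferase, took 0.340% ± 0.0941 of counts in refed and 2.03% ± 0.468 in fasted livers (SD, n = 3), a 6.98-fold rise in CPM (edgeR adjusted p = 0.000105). Ahsg, the plasma glycoprotein fetuin-A, rose 2.20-fold (edgeR adjusted p = 0.000463) and Apoa1, the main protein of high-density lipoprotein, 1.80-fold (edgeR adjusted p = 0.00167). C3, the central complement component, fell 1.75-fold (edgeR adjusted p = 0.0167). The 20 most abundant genes of each library took 24.9% ± 0.661 of counts in refed and 28.1% ± 1.82 in fasted livers (SD, n = 3). Of 414 Gene Ontology terms in the deposited table, 2 passed camera, both lower in fasted livers: cholesterol biosynthetic process (15 of 19 genes fell and 1 rose, camera adjusted p = 1.05e-09) and steroid biosynthetic process (14 of 28 fell and 7 rose, camera adjusted p = 0.0235). With an estimated correlation camera called 0 terms, with 8 at an unadjusted p under 0.05. Classical complement activation genes fell in 15 of 20 and rose in 0 by edgeR, and the term missed the threshold (camera adjusted p = 0.0661).

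Within the fasted group, fasted replicate 3 differed at least 2-fold from the mean of the other libraries in 212 lower and 198 higher genes of 8695 with a mean of at least 5 CPM, against at most 86 lower and 55 higher for any other library. With 0.5 CPM added, the lowest ratios among genes with a symbol and that mean belonged to G0s2, an inhibitor of lipid droplet lipase, at 3.17 CPM against 458 and 402, and to Pdk4, which shuts off pyruvate oxidation, at 17.8 CPM against 1312 and 849. Next came Inhbe, an activin subunit, at 0.518 CPM against 47.5 and 46.9, and the lipid droplet proteins Plin2, at 58.4 CPM against 1826 and 1335, and Cidec, at 21.2 CPM against 678 and 475. Fgf21, a fasting-induced hormone below a mean of 5 CPM, had 0 reads in fasted replicate 3, where 3 counts would be 0.0878 CPM of its total. It had 15.6 and 11.1 CPM in the other fasted libraries and 0.478 to 0.653 CPM in refed ones. The highest ratios of the same kind belonged to S100a9, a neutrophil protein, at 71.4 CPM against 0.420 and 0.683, to Cyp7a1, at 471 CPM against 5.94 and 8.63, to the retinoic acid hydroxylase Cyp26a1, at 92.8 CPM against 4.74 and 3.82, and to Cyp2c70, at 81.2 CPM against 3.72 and 5.03. Igfbp1 stood at 6642 CPM against 1551 and 926. The cell cycle list lay higher in this library by a median difference of 0.77. The Kupffer cell list lay at 1.28 in this library and 0.34 in fasted replicate 2, but at -1.57 in fasted replicate 1, which departed the most. Sqle, at 3.56 CPM against 3.36 and 3.32, stayed far below its refed level.

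The PPARalpha-regulated genes lay lower in fasted replicate 3 than in the other fasted libraries, with a median log2 difference of -1.61. Mixed-in refed RNA would need a median share of 79.5% to give this, while 16 genes at least 50 times higher in refed livers lay above the other fasted libraries by a median of only 0.445% of their refed level, so a mixture is argued against. The library's total count was 0.951 of the mean of the other 2, which argues against low depth, and the hepatocyte list lay 0.0861 above them on the log2 scale, which argues against dilution by other cells as the cause of this fall, though Kupffer cell, neutrophil, erythroid and stellate cell markers lay higher by 1.28, 1.17, 0.51 and 0.46. The way back to refed was taken as log2(CPM + 0.5), over members that differed from refed at least 2-fold, in either direction, in the other fasted libraries. The 79.5% is on the CPM scale over risen members only, so it is another measure. The oxidation list stood 113% of the way back (6 members) and the PPARalpha-regulated list 46.5% (17 members, lower quartile 29.3%). The fatty acid synthesis list stood at 15.7% (upper quartile 30.7%, so it overlaps the PPARalpha-regulated list). The cholesterol list stood only at 11.2% (upper quartile 18.1%), which argues against a state nearer to refed throughout. The members of the PPARalpha-regulated list did not fall alike. In fasted replicate 3 Cyp4a14 and Cyp4a10 stayed above refed livers, at 6466 CPM against 840 to 1249 and 3634 CPM against 727 to 978. Plin2 and Pex11a lay below refed livers, at 58.4 CPM against 264 to 293 and 49.7 CPM against 110 to 125. These genes are examples picked after their values were seen. A candidate explanation that stays open is a difference in PPARalpha activity or lipid supply between these libraries. S100a9 and the acute phase list were higher in the same library. The labels used here give no group or measurement that could test this explanation.

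The changed genes between fasted and refed livers numbered 7866, and the 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05, with 1 split, the real one, giving as many. The highest of the other splits gave 0 by edgeR, with at most 278 genes at an unadjusted p under 0.05 and at most 6 calls by DESeq2. Each of those splits mixes fasted and refed libraries within a group, which widens the spread there. Their low counts were therefore fixed in advance and are no measure of chance. Leaving the 20 most abundant genes out of the scaling moved the share of higher calls by only 0.03 percentage points, as TMM trims such genes anyway, so this tested nothing, and with library totals, where they act in full, that share went from 49.16% to 36.15%. A scaling shift of all genes would send the calls 1 way, and with library totals 2873 were higher and 5074 lower, which argues against it as the whole cause. The biological difference that the design names, fasting for 48 h, stays among the open explanations, as untested.

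The male-predominant genes that fell include families of near-identical copies, whose reads could be split. Without the Mup, Cyp2d, Cyp4a12, Serpina1 and Selenbp families, 8 of 8 remaining members fell. Their median log2 fold change was -1.99, in place of -1.60. The members that rose (Cyp2d9 and Cyp4a12b) or did not pass (Mup20) all belong to the removed families, so the count of 8 of 8 follows from the removal. The fall was not confined to these families, which argues against reads shared within them as its whole cause. Whether the remaining members share reads with other genes was not tested. The fast itself stays open, as untested.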
